A study of Mus musculus with 2 samples.

How the data were processed

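Splenic CD8+CD122+ and CD8+CD122- cells of C57BL/6 mice were sorted and their messenger RNA was amplified and hybridised to 2 two-colour Agilent arrays with the dyes exchanged between the arrays, per the labels. The scanner files were made with Agilent Feature Extraction, which the submitters' processing notes name, in version A.7.5.1 for array 1 and 8.1.1.1 for array 2 per the file headers. They hold spot and background intensity values on a linear scale per the file headers, flags of 0 or 1 per spot, processed signals with a spatially detrended background subtracted and a linear and LOWESS dye normalisation, and a log10 ratio of Cy5 over Cy3. The deposited value table of the series also holds log10 ratios. Set against the scanner files row by row, its values equal the scanner's log10 ratio with the sign turned on array 1 and as given on array 2, so that both columns are CD8+CD122- over CD8+CD122+ by the labels, which is opposite to the direction used here. The median of each column is 0, and 9.55% of values on array 1 and 5.64% on array 2 are exactly 0; whether this table was centred is not given in the sources used here, nor is a genome build, so no coordinates are printed.

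Each array holds 43790 spots, of which 2256 are controls, and 41174 different probes. Gene names in the scanner files are those of the array's design. Probes were named through a RefSeq gene table of the assembly GRCm38.p6 by accession (22233 probes), current symbol (5599) or unambiguous synonym (4256). That named 32088 probes (77.9%), and the other 9086 kept the file's own name, Klra15 among them. Mean spot intensities were background-corrected against the median local background with normexp and an offset of 50, and log2 ratios were normalised within each array by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Control spots and spots marked as outliers were left out, saturated spots were kept, and spots of a probe were averaged. A probe was kept if it was well above background in at least 1 population on both arrays (30794 probes), and a gene was represented by its brightest probe. This left 21895 genes, 16298 of them named in the reference table. The offset shrinks the ratios of dim genes, so folds are on that scale and understate the change of dim genes. No gene that passed the rule of size was below background in a population on both arrays, and none was saturated, so no bound was needed for them. Klre1, the 1 gene given as a bound, was set as the mean of CD8+CD122+ against the higher, per array, of the dim probe's own signal and the lowest signal among probes well above background, per channel after loess and Aquantile.

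Signs were turned so that every ratio is CD8+CD122+ over CD8+CD122-. Genes were fitted with limma (lmFit and eBayes, 1 coefficient, 1 residual degree of freedom, two-sided) with Benjamini-Hochberg adjustment over all genes tested, and called at an adjusted p under 0.05. A dye term would leave 0 residual degrees of freedom, and a dye effect common to both arrays cancels in their mean. A rule of size, at least 2-fold in the same direction on both arrays, was applied beside it and carries no p-value. Gene lists (27, each with at least 3 tested members) were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. With an estimated correlation 0 of the 11 lists that passed camera held, and the smallest adjusted p was 0.595. That version could hardly pass any list with 1 residual degree of freedom. The chemokine list had an estimated correlation of -0.11 and still an unadjusted camera p of 0.114. The test fry was run beside both versions of camera. List medians were set against 10000 random lists of the same size matched on brightness in 20 bins. Tests, lists, the rule for named genes and the alternatives were chosen before the data were examined, apart from those said to be added later.

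The named genes were Il2rb, Cd8a and Cd8b1, the 15 highest and 15 lowest called genes that have a gene symbol, up to 4 called members of each list, and Foxp3, Il10, Pdcd1 and Cxcr3 whether called or not. Because fewer than 10 genes were called by limma in each direction, the rule of size took the place of the call, as had been laid down. The 2 scans were not treated as batches, since each array is a scan of its own.

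The same steps were tested on simulated data of 21895 genes with the brightness and background of the real spots. The data carried a dye bias that depends on intensity. Random error was drawn per gene around limma's prior SD of 0.0996 with 1.79 prior degrees of freedom. The rule of size found 0% of 50 genes changed 1.5-fold, 0% of 50 changed 2-fold, 58% of 50 changed 4-fold and 100% of 50 changed 8-fold, with median estimated log2 ratios of 0.41, 0.71, 1.37 and 2.03. It also passed 24 unchanged genes, and 26 genes were 2-fold apart in opposite directions, a class that holds 0 genes in the real data. limma called 0% of the changed genes at each size and 0 unchanged genes.

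Alternatives covered background correction (none, offset 16, plain subtraction), the deposited processed signals, the value table, median centring in place of loess, no filter and a stricter filter on dim probes, the mean of all probes, scaling between arrays, an intensity trend and robust limma, each array alone, and the other list tests. A smaller fold in the rule of size, the removal of saturated probes and the interleukin receptor list without Il2rb were added after seeing the data.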

Results

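Gene expression was compared between CD8+CD122+ and CD8+CD122- T cells sorted from the spleens of C57BL/6 mice. CD122 is the beta chain of the receptors for interleukin 2 and interleukin 15. CD8+CD122+ cells are known as a population with memory-like and regulatory properties, and the series names them regulatory. Amplified messenger RNA of both populations was hybridised together on each of 2 two-colour arrays. Replicate 1 (array 1) carried CD8+CD122+ RNA in Cy5 and CD8+CD122- RNA in Cy3, and replicate 2 (array 2), a second trial, carried the dyes the other way round. The comparison therefore rests on 1 group of n = 2 arrays, and this number limits its precision. Among the spots that are not controls, 76.4% (CD8+CD122+) and 69.5% (CD8+CD122-) lay well above background on array 1, and 80.2% and 83.4% on array 2. Xist, the RNA that coats the inactive X chromosome, differed between the arrays in both populations. On the Xist probe that was brightest on array 2, the mean spot signals of CD8+CD122+ and CD8+CD122- were 92.9 and 104 on array 1 and 1440 and 1191 on array 2. Another Xist probe, the other one well above background in both populations on both arrays, gave 289 and 236 on array 1 and 526 and 762 on array 2. A further Xist probe gave 69.1 and 86.2, not well above background, on array 1, and 410 and 388, well above it, on array 2. The probes of the Y-linked genes Ddx3y, Eif2s3y and Kdm5d were well above background in both populations on both arrays. The labels do not state whether the second trial used new mice, so limma's p-values for single genes measure only the spread between these 2 arrays. The p-values of camera at its preset correlation set the members of a list against the other genes on the same arrays. They do not measure how a list varies between arrays or mice.

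The genes furthest above 2-fold in CD8+CD122+ cells included Ctla2a, the chemokine genes Ccl5 and Ccl4, Ifng and several probes for Ly49 receptor genes, and those furthest below included the integrin gene Itgae and the gut-homing receptor gene Ccr9. Of 21895 genes tested, 66 were at least 2-fold higher in CD8+CD122+ cells on both arrays and 23 at least 2-fold lower, and 0 genes passed that size in opposite directions. If the arrays were independent, 1.09 higher, 0.319 lower and 1.22 opposite genes would be expected. Every log2 ratio here is CD8+CD122+ over CD8+CD122-, the reverse of the direction of the series' own value table. Il2rb, which encodes the sorted marker CD122, had a log2 ratio of 2.47 ± 0.18 (SD, n = 2 arrays; 5.56-fold higher), with 2.60 on array 1 and 2.34 on array 2.

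No single gene passed limma's test after adjustment. It called 0 genes higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.151. At an unadjusted p under 0.05 it found 1393 genes, 625 higher and 768 lower, where 1095 would be expected by chance. The fits with an intensity trend and with robust limma likewise called 0 genes. On simulated arrays with the brightness and background of the real spots limma called 0% of 50 genes changed 8-fold. The rule of size found 100% of these, 58% of 50 changed 4-fold and 0% of 50 changed 2-fold, and it passed 24 unchanged genes of 21895. The simulated arrays held 26 genes 2-fold apart in opposite directions, against 0 on the real arrays. Their random error was thus heavier, and these rates may not hold for the real arrays. Because limma called 0 genes, calls of single genes below rest on size on both arrays and not on a p-value. Across genes, which are not independent replicates, the log2 ratios of the arrays had a Pearson correlation of 0.396 and a Spearman correlation of 0.102. The Pearson correlation was 0.0318 with median centring in place of loess. With the deposited processed signals the rule of size gave 141 higher and 64 lower genes, among them all 66 and 23.

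**Figure D1:**
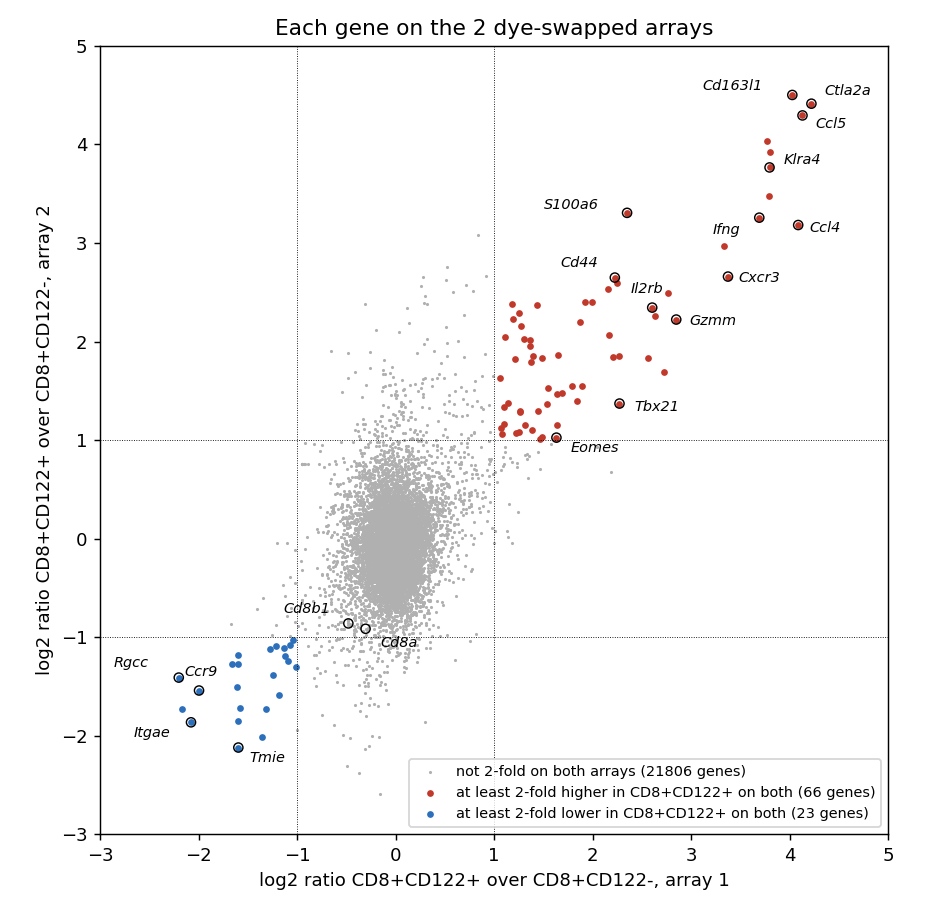
Log2 ratio of CD8+CD122+ over CD8+CD122- on array 1 (horizontal axis) and array 2 (vertical axis) for 21895 genes, 1 point per gene, with dotted lines at 2-fold. The 66 genes in red and the 23 in blue were at least 2-fold apart in the same direction on both arrays, circles mark genes named in the text, and no point lies 2-fold apart in opposite directions.

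The 66 genes higher in CD8+CD122+ cells had mean log2 ratios between 1.07 and 4.32, with 27 genes over 4-fold and 11 over 8-fold. Ctla2a and Ctla2b, which encode inhibitors of cysteine proteases in lymphocytes, had log2 ratios of 4.32 ± 0.14 (19.9-fold) and 3.86 ± 0.09 (14.5-fold; SD, n = 2 arrays, here and below). Cd163l1, a scavenger receptor gene with cysteine-rich domains, was 19.2-fold higher (4.26 ± 0.34). The chemokine genes Ccl5 and Ccl4 were 18.5-fold (4.21 ± 0.12) and 12.4-fold (3.63 ± 0.64) higher, and Ifng, the gene of interferon gamma, 11.1-fold (3.47 ± 0.31). Among the genes for Ly49 receptors, which bind MHC class I molecules on target cells, Klra16 had a log2 ratio of 3.91 ± 0.19, Klra4 of 3.78 ± 0.02, Klra15 of 3.63 ± 0.22 and Klra7 of 3.15 ± 0.25 (8.87-fold). These genes are near-identical copies, as are Ctla2a and Ctla2b, so the share of each member in its probe's signal is uncertain. Whether C57BL/6 mice carry each of these Klra members was not checked. Cxcr3, the receptor for chemokines induced by interferon gamma, had a log2 ratio of 3.02 ± 0.50 (8.09-fold), the calcium-binding protein gene S100a6 2.83 ± 0.68 (7.10-fold), the granzyme gene Gzmm 2.54 ± 0.44 (5.80-fold) and the surface antigen gene Ly6c1 2.45 ± 0.26 (5.45-fold).

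The 23 genes lower in CD8+CD122+ cells had smaller differences, with mean log2 ratios between -1.97 and -1.03. Itgae, which encodes the integrin chain CD103, was 3.92-fold lower (-1.97 ± 0.15), and Ccr9, the receptor for the gut chemokine CCL25, 3.41-fold lower (-1.77 ± 0.32). Plekho1, a pleckstrin homology domain protein gene, had a log2 ratio of -1.95 ± 0.31 (3.86-fold lower), Tmie -1.86 ± 0.37 (3.63-fold), and Rgcc, a regulator of the cell cycle, -1.81 ± 0.56 (3.50-fold). Dpyd, the first enzyme of pyrimidine breakdown, was 3.31-fold lower (-1.73 ± 0.18). Lrrc75b (-1.69 ± 0.47), the potassium channel subunit gene Kcnmb4 (-1.65 ± 0.10), Als2cl (-1.56 ± 0.07), the selenium carrier gene Selenop (-1.52 ± 0.29) and the carboxypeptidase gene Cpm (-1.47 ± 0.28) followed. Ramp1, a subunit of the receptor for calcitonin gene-related peptide, had -1.44 ± 0.23, the tetraspanin gene Cd9 -1.40 ± 0.30, Zmym4 -1.38 ± 0.29 and the actin-severing gene Gsn -1.31 ± 0.10. The adjusted p of limma for these 30 highest and lowest genes was 0.151 at the lowest. Of all genes that passed the rule of size, 35 had several probes. In 7 of these all probes passed it the same way, and in 7 a probe had the opposite sign. Among the 30 highest and lowest genes, probes of the same gene differed in size for several. Other probes gave log2 ratios down to 0.76 for Klra16 and 1.36 for Klra4, and up to 4.70 for Klra7, -1.03 for Itgae, 0.06 for Dpyd, -0.11 for Als2cl and -0.18 for Zmym4. With the mean of all probes Dpyd (-0.83), Als2cl (-0.84) and Zmym4 (-0.61) no longer reached 2-fold on both arrays.

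**Figure D2:**
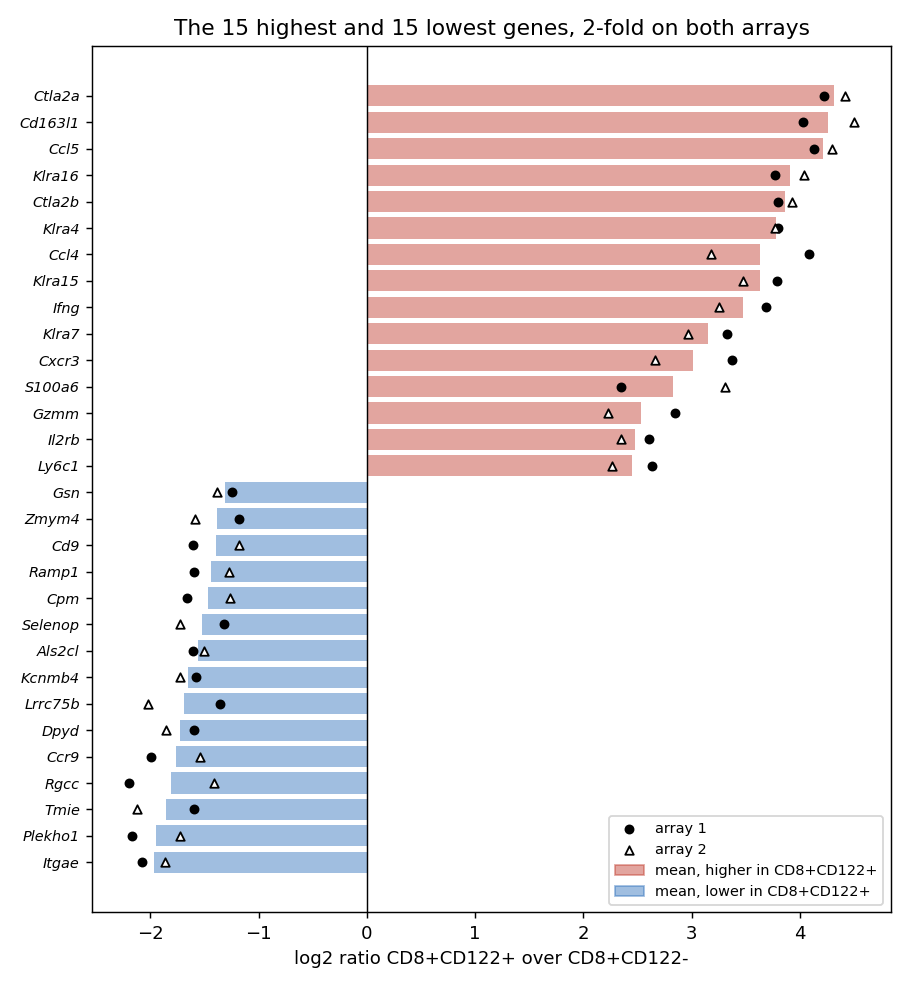
Log2 ratio of CD8+CD122+ over CD8+CD122- (horizontal axis) for the 15 highest and 15 lowest named genes that were 2-fold apart on both arrays, as the mean of both arrays (bars) with array 1 (filled circles) and array 2 (open triangles). On the brightest probe of each gene, values run from 4.32 for Ctla2a to -1.97 for Itgae, and both arrays lie on the same side of 0 for each gene.

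The CD8 chains themselves were measured next to the marker of the sort. Cd8a had a log2 ratio of -0.61 ± 0.43 and Cd8b1 of -0.67 ± 0.27, negative on both arrays and under 2-fold (limma's adjusted p 0.806 and 0.657). In the list of sorting markers and T cell receptor components, 1 of 16 members (Il2rb) was 2-fold higher, 0 were lower and 15 were neither, and 1 passed limma's threshold when adjusted over the list alone against 0 over all genes. This list had a median of -0.09 and a mean of 0.03, opposite in sign, and did not shift as a group (camera adjusted p 0.301).

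Memory and effector-memory T cell genes rose as a group in CD8+CD122+ cells. Of 36 members tested, 15 were at least 2-fold higher on both arrays, 0 lower and 21 neither, and 24 passed when adjusted over the list alone against 0 over all genes. The list median was 0.75, with 0.79 on array 1 and 0.77 on array 2 (camera adjusted p 5.79e-17; adjusted p = 0.595 with an estimated correlation). The central 95% of 10000 random lists matched on brightness had medians between -0.05 and 0.04. The 0.595, shared by each list that passed camera, comes from a version that could hardly pass any list with 1 residual degree of freedom. It is therefore not evidence that correlation between members accounts for the shifts. Beside Ccl5, Cxcr3, S100a6 and Ly6c1, the adhesion receptor gene Cd44 was among the 15 higher members at 2.44 ± 0.30, although 1 of its 3 probes gave 0.03. Naive T cell genes fell as a group, with a median of -0.17 (camera adjusted p 4.57e-05; adjusted p = 0.595 with an estimated correlation). The median was -0.26 on array 1 and -0.22 on array 2. Of 24 members, 0 were 2-fold higher, 3 were lower and 21 were neither, and 7 passed when adjusted over the list alone against 0 over all genes. The members lower by 2-fold were Itgae, Ccr9 and the lactate dehydrogenase gene Ldhb at -1.03 ± 0.01, whose other probe gave 0.12.

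Cytotoxic granule and killing genes rose, with a median of 0.37 (camera adjusted p 1.82e-07; adjusted p = 0.595 with an estimated correlation). Among 19 members, 2 were 2-fold higher, 0 lower and 17 neither, and 5 passed when adjusted over the list alone against 0 over all genes. Those 2 were Gzmm and Fasl, the gene of the Fas death ligand, at 1.90 ± 0.66, whose other probe gave 0.33. NK cell receptors and adaptors rose with a median of 0.13 (camera adjusted p 7.69e-09; adjusted p = 0.595 with an estimated correlation). The median was 0.31 on array 1 and 0.14 on array 2, and it ran from 0.08 to 0.40 over 10 other settings. Of its 24 members 4 were 2-fold higher, 0 lower and 20 neither, and 9 passed when adjusted over the list alone against 0 over all genes. The 4 were the Ly49 receptor genes Klra4, Klra7 and Klra6 (2.02 ± 0.25) and Klrc1, which encodes NKG2A (2.20 ± 0.29; 0.57 on its other probe). Markers of NK cells, a list that shares members with the former, also rose, with a median of 0.10 (camera adjusted p 0.000447; adjusted p = 0.595 with an estimated correlation). It was 0.23 on array 1 and 0.13 on array 2. Of its 9 tested members 1 was 2-fold higher, 0 lower and 8 neither, and 3 passed when adjusted over the list alone against 0 over all genes. That member was Eomes, a T-box transcription factor gene of memory CD8 T cells as well as of NK cells, whereas the adaptor genes Fcer1g (0.04 on array 1 and 0.05 on array 2) and Tyrobp (0.23 and -0.14) had values near 0. With the deposited processed signals the medians of several lists moved by over 1.5 times, to 1.31 for memory genes, 0.64 for cytotoxic genes, 0.40 for NK cell receptors, 0.20 for NK markers, 1.84 for chemokines, 0.17 for inhibitory receptors and 0.28 for apoptosis regulators.

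Chemokine genes had the highest median of the 27 lists, at 1.12, and rose as a group (camera adjusted p 6.56e-07; adjusted p = 0.595 with an estimated correlation). Of 9 members, 4 were 2-fold higher, 0 lower and 5 neither, and 4 passed when adjusted over the list alone against 0 over all genes. The 2-fold higher members were Ccl5, Ccl4, Xcl1 (1.72 ± 0.24), whose receptor XCR1 is borne by dendritic cells, and Ccl3 (1.26 ± 0.32). The list median equals the value of Cxcl10, a chemokine induced by interferon (0.46 on array 1 and 1.78 on array 2). It was 0.46 on array 1 alone, below the 0.79 of the memory list. Without the filter on dim probes it was 0.04, where camera still passed, and the memory list had no median below 0.68 in 10 settings. The chemokine list thus lost its rank in both cases. Chemokines were also the 1 list that passed fry (adjusted p 0.0232), which asks whether members move one way on balance. Receptors for chemokines, sphingosine phosphate and homing ligands were split: 4 of 30 members were 2-fold higher, 2 lower and 24 neither, and 12 passed when adjusted over the list alone against 0 over all genes. Cxcr3, Cd44, and, named after their values were seen, Cxcr5 (1.69 ± 0.46) and the integrin gene Itgb1 (2.14-fold; 0.02 as log2 ratio on its lowest probe) were higher, and Itgae and Ccr9 lower. The list as a whole had a median of 0.02 (camera adjusted p 0.136, and 0.0456 with median centring). Of 22 cytokine genes, 1 (Ifng) was 2-fold higher, 0 were lower and 21 were neither. In this list 1 passed when adjusted over the list alone against 0 over all genes, and the list did not shift (median 0.04, camera adjusted p 0.219).

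Regulatory T cell genes did not shift as a group (median 0.03, mean -0.07, opposite in sign; camera adjusted p 0.761). None of 23 members was 2-fold higher, 2 were lower and 21 were neither, and 2 passed when adjusted over the list alone against 0 over all genes. Foxp3, the lineage factor of CD4 regulatory T cells, had a log2 ratio of 0.03 ± 0.14, and Il10, the gene of the suppressive cytokine interleukin 10, -0.06 ± 0.03. Foxp3 was dim, with a mean log2 intensity of 6.09 against 11.4 for Il2rb, and ratios of dim genes are understated. Its value near 0 therefore does not show equal expression. Lag3, Fgl2 and Areg were on the array but were not tested. The lower members were Itgae and the receptor gene Gpr83 (-1.20 ± 0.10). Inhibitory receptors and ligands rose by a median of 0.08 (camera adjusted p 0.0404; adjusted p = 0.595 with an estimated correlation). The median was 0.03 on array 1 and 0.19 on array 2, with 4 members positive on both arrays, 1 negative on both and 7 of opposite signs. This call was lost with the stricter filter on dim probes (camera adjusted p 0.0766). Klrc1 was the 1 of 12 members that was 2-fold higher, 0 were lower and 11 neither, and 1 passed when adjusted over the list alone against 0 over all genes. Pdcd1, which encodes the checkpoint receptor PD-1, had a log2 ratio of -0.02 ± 0.23. It was dim as well (mean log2 intensity 6.63), so this value does not show equal expression either.

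Genes of interleukin 2, 7 and 15 receptor signalling had a median of 0.11 (camera adjusted p 0.0237; adjusted p = 0.595 with an estimated correlation). The median was 0.16 on array 1 and 0.12 on array 2. This list holds Il2rb, the marker of the sort, and without it, an alternative chosen after seeing the data, the list did not pass camera (19 members, median 0.09, adjusted p 0.104). Il2rb was the 1 of 20 members 2-fold higher, 0 were lower and 19 neither, and 2 passed when adjusted over the list alone against 0 over all genes. Cell cycle genes rose by a median of 0.21 with 0 of 36 members reaching 2-fold on both arrays (camera adjusted p 7.34e-13; adjusted p = 0.595 with an estimated correlation). Of these, 30 were positive on both arrays, 1 was negative on both and 5 had opposite signs, and 1 passed when adjusted over the list alone against 0 over all genes. Interferon-stimulated genes fell by 0.25 at the median (camera adjusted p 0.000202; adjusted p = 0.595 with an estimated correlation). Of 28 members 0 were 2-fold apart on both arrays, 16 were negative on both and 5 positive on both, and 0 passed either when adjusted over the list alone or over all genes. The median of this list was -0.09 on array 1 and -0.37 on array 2, the arrays that also differed in Xist. Immediate early and stress genes rose by a median of 0.14 (camera adjusted p 0.0189; adjusted p = 0.595 with an estimated correlation), with 0.21 on array 1 and 0.06 on array 2. Of 25 members 0 were 2-fold apart on both arrays and 11 had opposite signs on the arrays, and 0 passed either when adjusted over the list alone or over all genes.

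Transcription factors of CD8 T cell differentiation did not pass camera as a list (median 0.07, with -0.01 on array 1 and 0.10 on array 2, adjusted p 0.385), but did with median centring (adjusted p 0.00286). Of these, 4 of 32 members were 2-fold higher, 0 lower and 28 neither, and 6 passed when adjusted over the list alone against 0 over all genes. Tbx21, the gene of T-bet, had 1.82 ± 0.64, Nfil3 1.58 ± 0.66, Runx2 1.34 ± 0.40 (2.45 with its other probe) and Eomes 1.33 ± 0.43. Each missed the rule of size in some setting, Tbx21 with median centring, Nfil3 with the mean of all probes, Runx2 without background correction, and Eomes with 3 settings. Apoptosis regulators had a median of 0.11, with 0.03 on array 1 and 0.22 on array 2 (camera adjusted p 0.0737). Of 22 members 2 were 2-fold higher, 0 lower and 20 neither, and 0 passed either when adjusted over the list alone or over all genes. The higher members were Fasl and Bbc3, which encodes the pro-apoptotic protein PUMA (1.66 ± 0.51), and the list passed camera in 5 of 10 other settings. These were the deposited processed signals and the value table (adjusted p 0.0307 in each), an offset of 16 (0.0488), median centring (1.11e-05) and scaling between arrays (0.0424). Glycolysis genes (17 tested, median -0.00, mean 0.19, camera adjusted p 0.0799), fatty acid oxidation genes (16 tested, median -0.02, adjusted p 0.219) and cytosolic ribosomal protein genes (27 tested, median 0.04, adjusted p 0.314) did not pass camera, and no member was 2-fold apart on both arrays. The glycolysis median was 0.15 on array 1 and 0.03 on array 2, and 9 of 17 members had opposite signs on the arrays. Glycolysis genes passed with median centring (adjusted p 0.00286) and with scaling between arrays (0.0375), and ribosomal protein genes with median centring (0.00156). In each of these 3 lists 0 members passed either when adjusted over the list alone or over all genes.

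**Figure D3:**
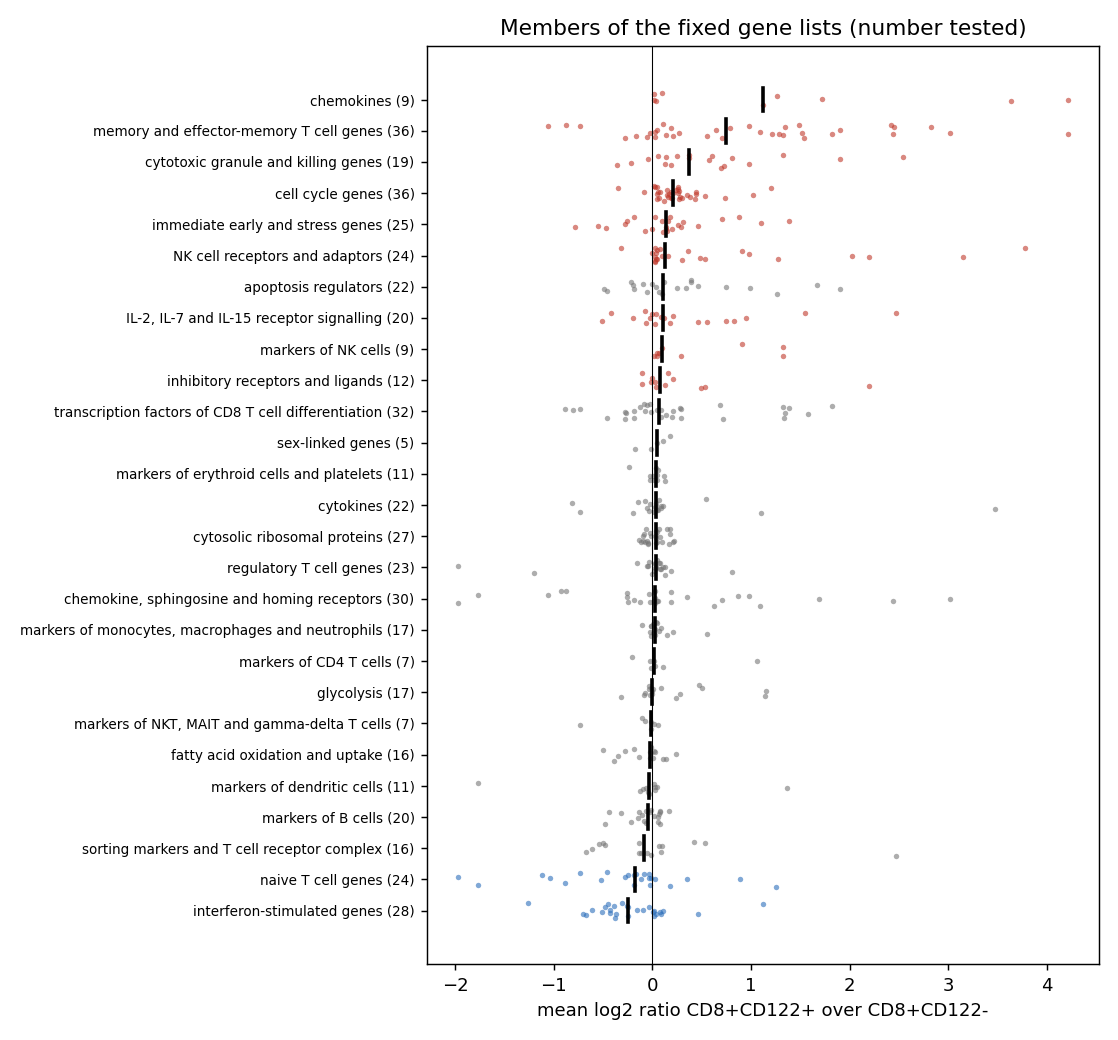
Mean log2 ratio of CD8+CD122+ over CD8+CD122- (horizontal axis) of each member of the 27 gene lists (vertical axis, number of members tested in brackets), with the list median as a black bar. Lists that passed camera at its preset correlation are red (higher) or blue (lower), others grey, and medians run from -0.25 for interferon-stimulated genes to 1.12 for chemokines.

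Apart from the NK cell markers above, no list of markers of other cell types passed camera. B cell markers (20 tested, median -0.05, camera adjusted p 0.219), markers of monocytes, macrophages and neutrophils (17 tested, median 0.02, adjusted p 0.219), of erythroid cells and platelets (11 tested, median 0.04, adjusted p 0.474) and of CD4 T cells (7 tested, median 0.02, adjusted p 0.880) had no member 2-fold apart on both arrays. In these lists 0 members passed either when adjusted over the list alone or over all genes. Markers of NKT, MAIT and gamma-delta T cells (7 tested of 17 fixed, median -0.01, adjusted p 0.219) had none either, with 1 passing when adjusted over the list alone against 0 over all genes. The fixed gamma and delta receptor genes and Zbtb16 were not found on the array, and Sox13 and Il17a were not tested. This list therefore says little about gamma-delta T cells. Among 11 dendritic cell markers (median -0.03, adjusted p 0.772), Zbtb46, a transcription factor gene of classical dendritic cells, was 2-fold higher (1.37 ± 0.11) and Ccr9 lower. The other 9 were neither, and 2 passed when adjusted over the list alone against 0 over all genes. The 5 sex-linked genes had a median of 0.05 between the populations (adjusted p 0.617), with 0 members 2-fold apart and 0 passing either when adjusted over the list alone or over all genes. Of the 44 named genes that were 2-fold apart on both arrays, 13 missed that rule in at least 1 of 10 other settings of background correction, normalisation, filter or probe choice. They were Ldhb in 4, Ccl3 and Eomes in 3 each, Gpr83 and Zmym4 in 2 each, and Als2cl, Dpyd, Fasl, Gsn, Nfil3, Runx2, Selenop and Tbx21 in 1 each.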

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

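The alternatives added after seeing the data were the 1.5-fold rule, the removal of saturated probes and the interleukin receptor list without Il2rb, which ended that list's camera call (adjusted p 0.104). limma called 0 genes in either direction under each of 12 other fits, with an adjusted p for Il2rb between 0.172 and 0.514. The 10 of these that change the values had 451 to 1600 genes at an unadjusted p under 0.05. The counts of 66 higher and 23 lower genes moved by over 1.5 times in these cases: 35 lower genes with an offset of 16, 36 with plain subtraction, 141 higher and 64 lower with the deposited processed signals and with the value table, 15 lower with the mean of all probes, and 160 higher and 80 lower at 1.5-fold. All 66 and 23 genes remained under the first 4 of these settings, while 55 and 15 of them did with the mean of all probes. In settings whose counts moved less, 53 and 14 of them remained with median centring and 55 and 18 with scaling between arrays. Without background correction 58 and 19 remained, with the stricter filter on dim probes 64 and 23, and without that filter all. Single arrays gave 94 to 255 higher and 39 to 179 lower genes, with fewer conditions to meet by construction. The correlation between arrays went from 0.396 to 0.0318 with median centring in place of loess, which also left medians of all genes of 0.11 on array 1 and -0.13 on array 2; the cause was not tested. Each of the 11 lists that passed camera kept its direction under each setting. No replicate block was added, because the ratio of each array already pairs its populations. The separate-channel fit planned was not run, because its intraspot correlation could not be estimated from 4 channels with 3 terms. Of the probes' spots, 69.5% to 83.4% lay well above background, which limits what dim genes can show.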

Other observations

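All tests of explanations in this part, and the genes named here, were chosen after the values were seen. Beyond the fixed lists, the genes 2-fold higher in CD8+CD122+ cells on both arrays included Itm2a, an integral membrane protein gene of T cells (2.12 ± 0.07, 4.34-fold; SD, n = 2 arrays; -0.07 on its other probe), Chsy1, a chondroitin synthase gene (2.06 ± 0.30, 4.17-fold), and Ifngr1, the ligand-binding chain of the interferon gamma receptor (1.71 ± 0.62, 3.28-fold). Nfkbiz (1.77 ± 0.73), Map3k8 (1.66 ± 0.41), Rgs1 (1.63 ± 0.33; 0.25 on its other probe), Dapk2 (1.59 ± 0.30; well above background in CD8+CD122- cells on 1 of 2 arrays), the sialyltransferase gene St3gal6 (1.55 ± 0.12; 0.78 on its other probe), Hopx (1.40 ± 0.34) and the thrombin receptor gene F2r (1.27 ± 0.01) were also among the 66. The scavenger receptor family gene 5830411N06Rik was 6.17-fold higher (2.63 ± 0.19) beside Cd163l1. On the other side stood the T cell adaptor gene Trat1 (-1.15 ± 0.09; -0.63 on its other probe) and the guanine nucleotide exchange factor gene Dock8 (-1.16 ± 0.21; -0.01 on the highest of its 5 probes).

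Memory-list members did not all lie on 1 side: the integrin gene Itga4 was lower on both arrays (-1.41 and -0.72; 0.04 on the highest of its 5 probes), and Cxcr6 was at -0.07 on array 1 and -1.68 on array 2. The lymph node homing receptor gene Ccr7 was at -0.92 on array 1 and 0.97 on array 2, and 25 genes were at least 1.5-fold apart on both arrays in opposite directions. The glucose transporter gene Slc2a1 (1.15 ± 0.50) and the hexokinase gene Hk2 (1.14 ± 0.75) had positive values on both arrays, although the glycolysis list passed camera with median centring and with scaling between arrays alone.

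On array 2, 345 genes were at least 2-fold apart that were not so in the same direction on array 1, among them the NF-kappa-B inhibitor genes Nfkbia (2.09 on array 2, 0.03 on array 1) and Tnfaip3 (1.74 and -0.04) and the STAT5 target gene Cish (2.51 and 0.58) on the higher side, and Ddit4 (-2.59 and -0.16) on the lower side. A dye effect alone, with no real difference, would give array 1 values of -1 or less in the direction of array 2. The median of these genes was 0.18. A dye effect of the probes added to a real difference would enlarge it on 1 array and shrink it on the other, so that stays open. Random error of array 2 with no real difference behind it would give 50% with the same sign on array 1, where 71.3% had it against 53.2% of all genes, but error added to smaller real differences stays open. Against ratios compressed on array 1 as a whole stands the memory list, whose median there was 1.02 times that on array 2. Other lists went both ways: 0.46 and 1.03 on arrays 1 and 2 for chemokines, 0.31 and 0.14 for NK cell receptors. Over all genes the SD of log2 ratios was 0.219 on array 1 and 0.333 on array 2, so compression stays open. Different mice or handling in the second trial stay open and cannot be told apart from the array itself: Xist was 13.3 times brighter on array 2 on 1 probe and 2.43 times on another, which may reflect another mix of mice but does not show why these genes differ.

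Of 13 Klra genes tested, 8 were 2-fold higher in CD8+CD122+ cells on both arrays. These are counts of genes as the probes are named, and 1 of the 8, Klra13-ps, is named as a pseudogene. Whether C57BL/6 mice carry each member was not checked. The median log2 ratio was 1.67 over all 13 and 2.68 over those 8, which were selected for their size. NK cells in the sorted gate, which the CD8 sort would largely remove, are only weakly argued against as the whole source by the fixed list of NK cell markers. Its 9 tested members had a median of 0.10 and an SD of 0.56, with 5 of them within 0.25 of 0, Fcer1g and Tyrobp among these. Tyrobp was dim (mean log2 intensity 6.35), where ratios are understated, and Ncr1, Klri2, Itga2, Serpinb9b and Styk1 were not tested. A smaller share of NK cells stays open, since Gzma (0.99 and 1.65 on arrays 1 and 2) was positive on both arrays and Klre1, not well above background in CD8+CD122- cells, was at least 1.84-fold higher (limma's adjusted p 0.58; log2 ratio 0.01 on its other probe). Cross-hybridisation among the near-identical Klra copies may account for the signal of any 1 of the 8. Log2 ratios ran from 0.31 for Klra5 to 3.91 for Klra16 with an SD of 1.28. Probes of the same gene differed as well, from 0.76 to 3.91 for Klra16 and from 1.36 to 3.78 for Klra4. They differed less for Klra3 (0.36 to 0.55) and Klra5 (0.31 to 0.38). Unequal ratios therefore cannot tell 1 common signal from several, and which members are expressed stays open. Ly49 expression by the CD8+CD122+ cells themselves remains a hypothesis.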
